A study of Mus musculus with 9 samples.

How the data were processed

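RNA sequencing had been run on myeloid cells of C57BL/6 mice, with total RNA taken up with a Macherey-Nagel kit and paired-end reads made on an Illumina NovaSeq instrument, per the labels' protocols. The 9 libraries fall into 3 groups of 3, told apart by their titles and genotype labels: Gr_1 and fl, both of wild type, and KO, of Socs3 knockout. Each title also carries a letter (A, B or C). What the names Gr_1 and fl stand for is not spelled out in the labels, so both are used here as they stand. The labels do not say whether libraries of a group came from separate animals, and p-values measure only the spread between these samples, which may be technical.

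The deposited table holds 1 column of FPKM values per library for 54532 Ensembl genes, per the file headers. FPKM is the number of fragments per kilobase of exon and per mega (M) fragments. The submitters' processing notes name featureCounts (version 1.5.0-p3), DESeq2 (version 1.16.1) and the mouse builds mm10 and GRCm38, with no role or order. The aligner is not given in the sources used here. The deposited FPKM values were multiplied by the exon length of each gene in GENCODE M21, and the smallest step gave the fragments behind each value. Of the values under 1000 fragments, between 97.2% and 97.5% per library came out whole within 0.02 fragments. The recovered totals lay between 18.3 and 21.5 M fragments per library and the denominators implied by the values between 16.0 and 22.0 M. These denominators followed median-of-ratios size factors within 0.00035 on the log2 scale and departed from the library totals by up to 0.222. Gene symbols came from GENCODE M21 (54409 genes matched, 123 did not), as did all coordinates, which are on GRCm38.

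Depth sets a floor on each value. For a gene with 1 kilobase of exon, 3 fragments correspond to between 0.136 and 0.187 FPKM, depending on the library. This floor covers counting error only.

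Genes at 1 FPKM or more in at least 3 libraries were kept (12289 genes), and log2(FPKM + 1) was fitted with limma (version 3.58.1, R 4.3.3) with a mean-variance trend. All 9 libraries entered 1 fit with 1 term per group and no block, which leaves 6 residual degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Fold values are ratios of mean FPKM, while log2 changes are fitted on log2(FPKM + 1), so the fold is not 2 to the power of the log2 change. Errors beside a log2 change are standard errors from the fit, and errors beside a level are standard deviations over 3 libraries. For single genes the exact two-sided permutation test of 3 against 3 libraries was also run. Its smallest possible p is 0.1, so it cannot pass 0.05. Figures and smaller tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

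The test, the filter, the comparisons, the gene lists, the rule for naming genes and the alternative settings but 3 were all chosen before the data were examined. The rule names, for KO against fl and for Gr_1 against fl, the 10 genes with the largest rise and the 10 with the largest fall among called genes with a plain symbol, no overlap between the libraries of the groups, and at least 1 FPKM in the higher group. For KO against Gr_1 it names 5 and 5. From each list it adds up to 2 called members per direction with the smallest adjusted p, or the 2 most abundant members where none is called. Socs3, Mir155hg, Cebpb, Stat3, Ctnnb1, Map1lc3b, Becn1, Sqstm1, Atg5, Mtor, Arg1, Nos2, Ly6g, Ly6c2, Itgam and Adgre1 are named whatever their values.

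The 30 gene lists cover STAT3 targets and cytokine feedback, autophagy, lysosome, Wnt pathway components, Wnt target genes, the mTOR pathway, myeloid transcription regulators, suppressor cell effectors, early granulocyte genes, late neutrophil genes, monocyte genes, macrophage genes, MHC class II presentation, dendritic cell genes, B and plasma cell genes, T cell genes, NK cell genes, eosinophil, basophil and mast cell genes, erythroid and platelet genes, progenitor genes, epithelial and tumour cell genes, fibroblast and endothelial genes, cell cycle, interferon response, inflammatory cytokines and chemokines, hypoxia and glycolysis, apoptosis and survival, immediate early and heat shock genes, mitochondrially encoded genes, and ribosomal protein genes. Each list was tested in each comparison with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists. Camera with an estimated correlation and fry were run as alternatives. Camera with an estimated correlation called 0 of the 30 lists in each of the 3 comparisons. At an unadjusted p under 0.05 it gave 6 lists for KO against fl, 2 for Gr_1 against fl and 1 for KO against Gr_1. Members called were counted over all genes tested and also adjusted over the list alone.

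The procedure was tested on simulated data. For KO against fl, with 11877 genes in the fit, limma recovered 58.7% of 63 genes changed 1.5-fold, 75.4% of 65 changed 2-fold and 90.6% of 64 changed 4-fold, with 3 false calls (2.04% of calls). It made 1 call in a simulation with no change. Each library was drawn independently, with 1 spread per gene pooled over the 3 groups. These rates do not cover a wider spread in 1 group or libraries that share RNA. In a list simulation for KO against fl, over 12279 genes, camera called the 1 changed list and none of the 29 unchanged lists. Its genes were drawn independently, so it cannot show how camera at the preset correlation treats lists whose members move together. Estimated correlations in the data reached 0.586 for late neutrophil genes and 0.874 for ribosomal protein genes.

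The alternative settings were limma without trend, quantile normalization, median centring, a pseudocount of 0.1, no filter, a stricter filter (1 FPKM in every library of a group and a mean of 5), only the 2 groups compared, the title letter as a block, leaving out each library in turn, leaving out the 10 most abundant genes by mean share over all libraries with the rest rescaled, and a threshold that adds a change of at least 1 on the log2 scale. Scaling to library totals, scaling to equal sums and voom on the recovered fragments were chosen after seeing the data. All columns of values were used.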

Results

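Total RNA of mouse myeloid cells was profiled in 9 libraries, with 3 libraries in each of the groups Gr_1, fl and KO. The fl and Gr_1 mice were labelled wild type and the KO mice were labelled as lacking Socs3, the suppressor of cytokine signalling that limits signalling through STAT3. Recovered depth was alike in the 3 groups, at 19.5 ± 1.27 M fragments in fl, 19.6 ± 0.543 M in KO and 19.7 ± 1.58 M in Gr_1 (mean ± SD, n = 3 each). Between 11347 and 11700 genes per library reached 1 FPKM. The 10 most abundant genes of each library, which need not be the same 10, held 38.9 ± 0.473% of all FPKM in Gr_1, 27.9 ± 2.30% in KO and 24.7 ± 0.529% in fl. By mean share over all libraries the neutrophil granule and cytosol genes S100a9, S100a8, Ngp and Camp came first. Replicates differed by more than sampling noise in every pair, with a mean chi-square per gene from 4.13 to 45.3. The first principal component held 70.2% of the variance and placed the Gr_1 libraries at one end, the fl libraries at the other and the KO libraries between them. The second held 10.7% and set the KO libraries (-11.8, -25.9 and -18.0) apart from both fl (11.5 to 20.8) and Gr_1 (2.54 to 5.57). Library KO B carried Xist, the RNA of the inactive X chromosome in females, at 58.5 FPKM and 0 fragments of the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, while KO A carried the Y-linked genes at 26.5 FPKM together and Xist at 0.0028 FPKM. Library KO C carried both, with Xist at 26.3 FPKM and the Y-linked genes at 14.2 FPKM. It may share RNA with KO A and KO B. If so, the 3 libraries labelled KO are not independent, and their SDs and the p-values that rest on them are too small. All fl and Gr_1 libraries carried the Y-linked genes and had Xist at or below 0.0104 FPKM, so sex differed between groups as well as within KO.

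Socs3 was not lower in the libraries labelled KO. Its levels there were 9.23, 6.76 and 8.37 FPKM (8.12 ± 1.25, SD, n = 3), against 3.87, 4.02 and 3.40 FPKM in the fl libraries (3.76 ± 0.318). Gr_1 libraries held 37.0, 36.6 and 33.0 FPKM (35.5 ± 2.21). The fitted change from fl to KO was a rise of 0.93 ± 0.11 in log2(FPKM + 1) (limma, adjusted p = 0.00136, higher in 3 of 3 libraries), and the ratio of the mean FPKM was 2.16. The exact two-sided permutation test gave p = 0.1, the smallest value 3 against 3 libraries allow. These values rest on 182 to 246 Socs3 fragments per fl library and 425 to 530 per KO library. The gene, ENSMUSG00000053113, lies on the minus strand of chromosome 11 from 117966079 to 117970047 (GRCm38), and the values sum over its annotated exons. A knockout that leaves a transcript need not lower this sum, and which part of the gene was targeted is not given in the labels, so the values do not show the genotype. The groups are named below as labelled, and every direction given for the libraries labelled KO rests on that label.

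A far lower level was seen for another gene. Lyz2, which encodes lysozyme M of neutrophils and macrophages, had 56.3 ± 3.30 FPKM in the libraries labelled KO against 9165 ± 725 in fl and 10663 ± 163 in Gr_1 (n = 3 each). It was 163-fold lower than in fl, a log2 change of -7.32 ± 0.10 (limma, adjusted p = 1.42e-09), and 189-fold lower than in Gr_1. Lyz2 (ENSMUSG00000069516) lies on the minus strand of chromosome 10 from 117277331 to 117282321. Its close paralog Lyz1 was higher in the libraries labelled KO, at 34.4 ± 16.6 FPKM against 5.86 ± 0.631 in fl, and since the paralogs share sequence the division of fragments between them is uncertain. Lyz1 was chosen after its values were seen.

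**Figure D1:**
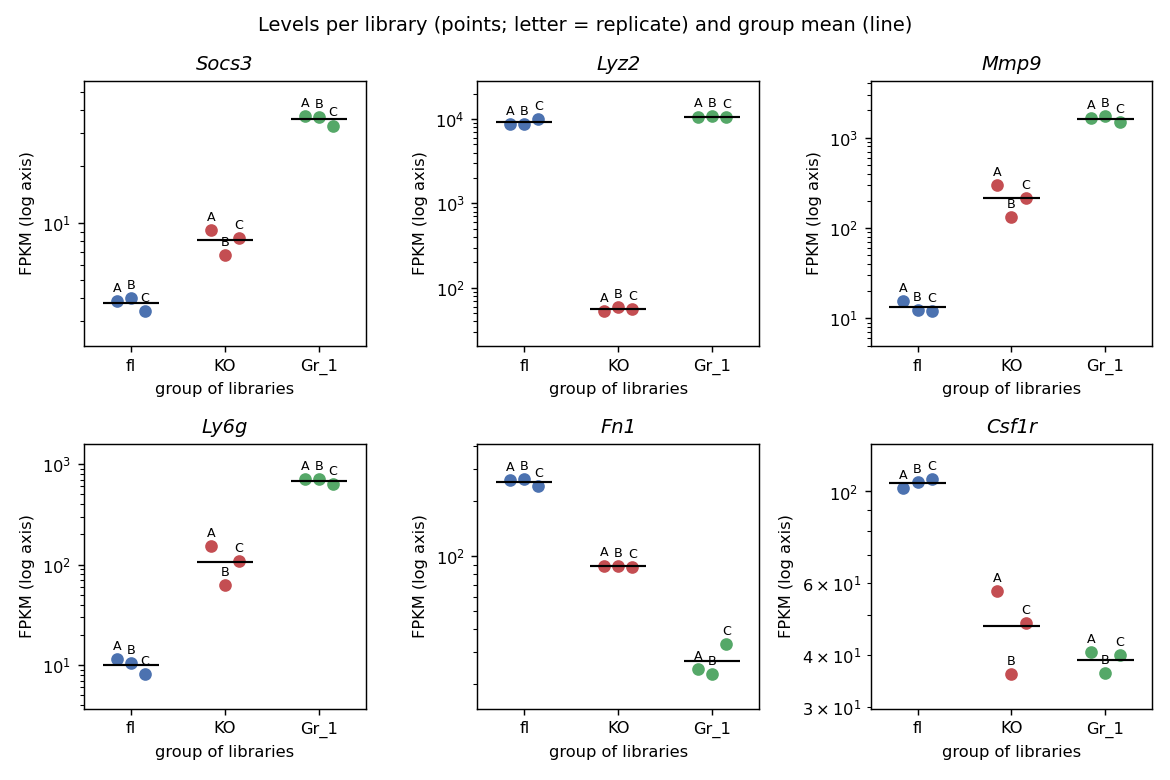
Level of 6 genes in each library, in FPKM on a log axis, by group; points are single libraries marked by letter and lines are group means. Socs3 sits at 6.76 to 9.23 FPKM in the libraries labelled KO and at 3.40 to 4.02 in fl, while Lyz2 sits at 53.2 to 59.8 against 8670 to 9998.

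In the comparison of the libraries labelled KO with fl, neutrophil genes stood higher in the libraries labelled KO and monocyte genes lower. Mmp9, a matrix metalloproteinase of neutrophil granules, rose from 13.4 ± 2.05 to 215 ± 81.9 FPKM, a log2 change of 3.84 ± 0.25 (limma, adjusted p = 0.000216). Ly6g, a surface antigen of mouse neutrophils, rose 10.7-fold to 107 ± 44.9 FPKM (adjusted p = 0.00046), with 152, 62.0 and 108 FPKM in KO A, KO B and KO C. The stefin Stfa2l1 rose from 0.189 to 26.3 FPKM, on 5 fragments in fl and 689 in KO. The formyl peptide receptor gene Fpr1 rose by 3.25 on the log2 scale, the chemokine receptor gene Cxcr2 by 2.57, the collagenase gene Mmp8 by 2.82 and the cytokine gene Il1b by 3.03. Asprv1, Scrg1 and H2-Q10 complete the 10 largest rises, with log2 changes from 2.75 to 3.02. Large falls after that of Lyz2 included those of Tppp3 and of the fibronectin gene Fn1, from 257 ± 12.1 to 88.3 ± 0.843 FPKM. Thbd, the stress-response factor gene Atf3, Mcub, Arhgef10l, Galnt9 and the scavenger receptor gene Lrp1 also fell, with log2 changes from -1.51 to -1.38. Mmp9 lies on chromosome 2 from 164940780 to 164955850 and Fn1 on chromosome 1 from 71585520 to 71653200.

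In all, limma called 1352 of 12289 genes, 551 higher and 801 lower in the libraries labelled KO, and 3233 genes had an unadjusted p under 0.05. Over all 12289 genes, called or not, the 3 KO libraries lay apart from the 3 fl libraries in 31.4%, where chance gives 10%. Of the 1352 called genes, 228 changed by at least 1 on the log2 scale, 127 up and 101 down. Calls numbered 573 without KO C, 730 without fl B and 818 without fl A, and 568 of the 573 were among the 1352 with the same sign. The balance between directions depended on the scaling, with 767 higher and 585 lower after the 10 most abundant genes were left out.

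Late neutrophil genes formed the list with the most rises. Of 28 members tested, 16 rose and none fell (21 and 1 adjusted over the list alone), among them Stfa2l1 and Mmp9, with a camera adjusted p of 1.83e-16 and an adjusted p = 0.206 with an estimated correlation. Suppressor cell effectors, genes by which myeloid cells restrain T cells, had 5 of 21 members higher and 2 lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.000605, and adjusted p = 0.363 with an estimated correlation). The risers were Mmp9, Il1b, Entpd1, Nt5e and the arginase gene Arg2, which rose from 0.237 ± 0.108 to 5.72 ± 3.16 FPKM. The fallers were Tgfb1, no longer called without any single library except fl A and fl C (adjusted p up to 0.111), and the heme oxygenase gene Hmox1, no longer called without any except KO A (up to 0.128). No early granulocyte gene was called (camera adjusted p = 0.313, 0 of 14 adjusted over the list alone, 1 at an unadjusted p under 0.05 and 0 with voom). Elane, the neutrophil elastase gene, had 2387 ± 745 FPKM in the libraries labelled KO and 2402 ± 530 in fl. Without KO A or fl C the early granulocyte list was called higher, at adjusted p of 0.013 and 0.0401, as it was with quantile normalization (adjusted p = 0.0243).

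Many monocyte, macrophage and antigen presentation genes were lower. Of 22 monocyte genes, 11 fell and 1 rose (12 and 2 adjusted over the list alone, camera adjusted p = 0.000169, and adjusted p = 0.228 with an estimated correlation). Csf1r, the receptor for macrophage colony-stimulating factor, fell from 105 ± 2.69 to 47.1 ± 10.6 FPKM. The marker genes Ly6c2, Itgam and Adgre1 were not called, with log2 changes of -0.14, 0.18 and -0.25 (adjusted p = 0.244, 0.343 and 0.378). Itgam was called higher without KO B (0.31, adjusted p = 0.04995). The riser was Ifitm6, no longer called without any single library except KO B (adjusted p up to 0.128). Among 22 macrophage genes, 8 fell and 2 rose (11 and 3 adjusted over the list alone, camera adjusted p = 0.00899, and adjusted p = 0.312 with an estimated correlation). The glycoprotein gene Cd68 fell from 105.5 ± 4.09 to 45.5 ± 7.81 FPKM and the lipid carrier gene Fabp5 from 10.1 ± 1.11 to 4.13 ± 0.464, while the iron exporter gene Slc40a1 rose from 10.6 to 16.2. Cd9 also rose, but not without KO C, Gr_1 A or any single fl library (adjusted p up to 0.0862). Without KO B the macrophage list had 5 falls and its adjusted p was 0.0807, with the stricter filter its adjusted p was 0.127, and without KO C or fl A it had 4 falls, against 5 without fl B or fl C.

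MHC class II presentation had 11 of 15 members lower and 1 higher (11 and 2 adjusted over the list alone, camera adjusted p = 1.18e-05, and adjusted p = 0.234 with an estimated correlation). The class II beta chain gene H2-Ab1 fell from 153 ± 18.1 to 75.2 ± 4.64 FPKM and the peptide loading gene H2-DMa from 49.4 ± 2.71 to 25.9 ± 0.704. The riser was H2-Oa, which stayed called in 3 of the 9 fits that left out a library (without Gr_1 A, Gr_1 C or fl B). Lysosome genes had 17 of 34 members lower and none higher (19 and 0 adjusted over the list alone, camera adjusted p = 9.74e-09, and adjusted p = 0.189 with an estimated correlation). Psap, precursor of the saposins that help lipid breakdown, fell from 1362 ± 107 to 592.5 ± 97.8 FPKM and the acid lipase gene Lipa from 29.6 ± 1.54 to 16.8 ± 0.918. Without KO C the lysosome list had 10 falls. Of 28 myeloid transcription regulators, 8 fell and 1 rose (10 and 3 adjusted over the list alone, camera adjusted p = 0.00701, and adjusted p = 0.176 with an estimated correlation). Irf5, an interferon regulatory factor of macrophages, fell from 84.9 ± 1.12 to 33.5 ± 4.69 FPKM. Gata2 rose, but stayed called in 3 of the 9 fits that left out a library (without Gr_1 C, fl C or KO A). Immediate early and heat shock genes had 7 of 22 lower and 1 higher (10 and 2 adjusted over the list alone, camera adjusted p = 0.00132, and adjusted p = 0.256 with an estimated correlation). Fos fell from 570 ± 5.72 to 261 ± 15.6 FPKM, and Egr1 rose but not without KO B, KO C, fl A or fl B (adjusted p up to 0.0738).

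The series title names autophagy, Wnt signalling, C/EBPβ and a microRNA. The calls among genes of these themes are to be read beside the 1352 called of all 12289 genes tested. Of 44 autophagy genes, 1 rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.693). Wipi1 rose, and Uvrag, Atg4c and Rubcn fell. None of the 4 was called without KO C, where 0 of 44 passed with limma, while without KO A 0 rose and 5 fell and without KO B 3 rose. Without fl A 0 rose and 1 fell, and without fl B 0 rose and 2 fell. With all libraries 3 autophagy genes were higher and 8 lower at an unadjusted p under 0.05. The list's median log2 change was -0.02, and 0.05 after the 10 most abundant genes were left out. Map1lc3b, which encodes the LC3B protein of autophagosome membranes, had 19.4 ± 2.16 FPKM in the libraries labelled KO and 18.8 ± 1.03 in fl (log2 change 0.04 ± 0.08, adjusted p = 0.81). The log2 changes of Becn1, Sqstm1, Atg5 and Mtor were 0.05, -0.01, -0.04 and -0.03, none called. Cebpb, the gene of C/EBPβ, had 106 ± 30.6 FPKM against 178 ± 43.4, a log2 change of -0.75 ± 0.22 that missed the threshold (adjusted p = 0.0677) although the 3 libraries of the groups lay apart (10% by chance). Mir155hg, the host transcript of the microRNA, had 2, 11 and 3 fragments in the libraries labelled KO and 0, 1 and 1 in fl, and did not reach 1 FPKM in 3 libraries, so it was not tested.

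Wnt pathway components had 1 of 18 tested members lower (1 adjusted over the list alone, camera adjusted p = 0.228). This was the receptor gene Fzd4, not called without KO B or KO C and not tested without an fl library. The median of this list turned from -0.05 to 0.02 when the 10 most abundant genes were left out. Ctnnb1, the gene of beta-catenin, had 33.9 ± 0.768 FPKM against 35.5 ± 0.348 (adjusted p = 0.454). Of 12 Wnt target genes, Tcf7 and Fosl1 rose and none fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.157). Tcf7 is also a gene of T cells. Neither was called without KO C, fl A or fl B, nor Fosl1 without KO B or fl C, and the list itself was called higher without Gr_1 A, Gr_1 B or Gr_1 C, at adjusted p of 0.0216, 0.0298 and 0.0209. Of 27 STAT3 targets and cytokine feedback genes, 4 rose and 5 fell (9 and 8 adjusted over the list alone, camera adjusted p = 0.897). Socs3, Il1rn, Il1r2 and Fgl2 rose. The interleukin 6 receptor genes Il6ra and Il6st fell, from 36.9 ± 1.46 to 18.7 ± 1.90 FPKM and from 6.20 ± 0.562 to 3.13 ± 0.173, with Il10ra, Pim1 and Junb. Without KO C 1 member rose, without fl B 2, and Il1rn was not called without KO C, fl A or fl B. Stat3 had 28.7 ± 2.08 FPKM against 29.5 ± 2.24. In the mTOR pathway 0 of 35 rose and 3 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.325), namely Lamtor5, Rraga and Deptor, and none of these was called without KO C, with 1 lower without fl B. At an unadjusted p under 0.05, 1 mTOR gene was higher and 6 were lower, and the list's median turned from -0.06 to 0.01 without the 10 most abundant genes.

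Genes of other blood cells were higher in the libraries labelled KO. T cell genes rose in 9 of 10 tested members (9 adjusted over the list alone, camera adjusted p = 4.14e-10, and adjusted p = 0.0554 with an estimated correlation), such as the T cell receptor subunit gene Cd3d, from 0.393 ± 0.189 to 2.29 ± 0.294 FPKM. NK cell genes rose in 6 of 9 (8 adjusted over the list alone, camera adjusted p = 6.7e-06, and adjusted p = 0.256 with an estimated correlation), with Ncr1 at 3.17 ± 1.17 against 0.743 ± 0.341 FPKM. Of 22 T cell and 14 NK cell genes listed, 10 and 9 passed the filter. A gene could pass through the libraries labelled KO alone, which favours rises. Trac was such a gene, at 2.27 FPKM there against 0.401 in fl and 0.446 in Gr_1. Klrb1c was another, at 1.79 against 0.59 and 0.41. Ncr1 too had means under 1 FPKM in fl and Gr_1 (0.743 and 0.268). Eosinophil, basophil and mast cell genes rose in 9 of 20 (13 adjusted over the list alone, camera adjusted p = 1.39e-08, and adjusted p = 0.228 with an estimated correlation). Cpa3, a mast cell carboxypeptidase, rose from 4.96 ± 0.812 to 18.3 ± 0.164 FPKM, and Ms4a2, the beta subunit of the IgE receptor, from 2.96 ± 0.275 to 7.72 ± 0.852. Progenitor genes had 6 of 13 higher and 1 lower (11 and 1 adjusted over the list alone, camera adjusted p = 6.87e-06, and adjusted p = 0.154 with an estimated correlation), with Cd34 at 5.84 ± 1.28 against 2.01 ± 0.352 FPKM and the faller Cd48 at 39.0 ± 2.03 against 62.3 ± 6.27. These 3 counts depended on single libraries, with 1 NK cell, 2 eosinophil, basophil and mast cell, and 2 progenitor genes higher without KO C. The counts were 3, 4 and 2 without fl A and 3, 3 and 2 without fl B, and 3 NK cell genes were higher without fl C. Erythroid and platelet genes had 3 of 16 higher (5 adjusted over the list alone, camera adjusted p = 4.64e-05, and adjusted p = 0.145 with an estimated correlation), the carbonic anhydrase genes Car1 and Car2 and the globin gene Hbb-bt, but 0 without KO C with limma and 1 without fl A. At an unadjusted p under 0.05, 10 of these genes were higher.

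B and plasma cell genes gave 0 calls of 18 with limma (0 adjusted over the list alone, camera adjusted p = 0.693), with 3 higher and 2 lower at an unadjusted p under 0.05 and 0 with voom. The light chain gene Igkc had 316 ± 97.8 FPKM against 200 ± 40.3. Without KO A, 1 B cell gene rose and 2 fell. Dendritic cell genes had 2 of 12 higher, Siglech and Cd24a, and 3 lower, Clec10a, Batf3 and Cd209a (3 and 4 adjusted over the list alone, camera adjusted p = 0.693). The dendritic cell genes that rose numbered 0 without KO C and 1 without KO A, KO B, fl A or fl B. Siglech, at 1.615 FPKM against 0.446 in fl and 0.530 in Gr_1, passed the filter through the libraries labelled KO, which favours a rise. Fibroblast and endothelial genes had 2 of 8 higher, Thy1 and Pecam1 (3 adjusted over the list alone, camera adjusted p = 0.000828, and adjusted p = 0.145 with an estimated correlation), and neither was called without KO C, fl A or fl B, nor Pecam1 without KO B or Gr_1 A. Thy1 is also a T cell gene on the list of that name, and with quantile normalization the fibroblast list had an adjusted p of 0.0583. Of 4 epithelial and tumour cell genes none was called (3 adjusted over the list alone, 3 higher at an unadjusted p under 0.05, 2 with voom), with a camera adjusted p of 0.0221 and an adjusted p = 0.206 with an estimated correlation. Among them was the neutrophil granule gene Lcn2, at 1226 ± 323 against 775 ± 28.9 FPKM, and the list was not called without fl A or fl B (adjusted p = 0.0755 and 0.0554) or with no filter (adjusted p = 0.173).

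Inflammatory cytokines and chemokines had 2 of 20 higher, Il1b and Csf1, and 3 lower, Ccl2, Ccl9 and Il18 (6 and 3 adjusted over the list alone, camera adjusted p = 0.473). Ccl2, a monocyte chemoattractant, fell from 5.77 ± 0.362 to 1.89 ± 0.287 FPKM, and Csf1 was not called without KO C or fl B, while 4 members rose without KO A. Of 29 interferon response genes only Mx2 was called, lower, with 0 adjusted over the list alone and 5 lower at an unadjusted p under 0.05 (camera adjusted p = 0.179). Mx2 was not called without any single fl library, KO B or KO C, and the interferon list was called lower without KO A (adjusted p = 0.00189, 3 members lower). Hypoxia and glycolysis genes had Car9 higher and Ndrg1 lower of 24 (0 and 1 adjusted over the list alone, camera adjusted p = 0.341), and neither was called without KO C. Car9 was called without Gr_1 C or KO A and in no other fit that left out a library, and with quantile normalization the list was called higher (adjusted p = 0.0243). Apoptosis and survival genes had Bbc3, Bmf and Bcl2a1d lower of 25 (5 lower adjusted over the list alone, camera adjusted p = 0.179). None of 40 cell cycle genes was called with limma (0 adjusted over the list alone, 1 lower at an unadjusted p under 0.05, 0 with voom, camera adjusted p = 0.897). The replication clamp gene Pcna had 162 ± 13.8 FPKM against 172 ± 12.7. None of 13 mitochondrially encoded genes was called with limma (0 adjusted over the list alone, 1 higher at an unadjusted p under 0.05, 0 with voom, camera adjusted p = 0.804), but 3 were lower without fl C, where the list was called (adjusted p = 0.000888). None of 32 ribosomal protein genes was called (0 adjusted over the list alone, 1 lower at an unadjusted p under 0.05, 0 with voom). As a list they were lower by camera (median log2 change -0.21, adjusted p = 0.00149), with an adjusted p = 0.733 with an estimated correlation, 0.292 with quantile normalization, 0.277 without KO A and 0.0821 without fl C.

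**Figure D2:**
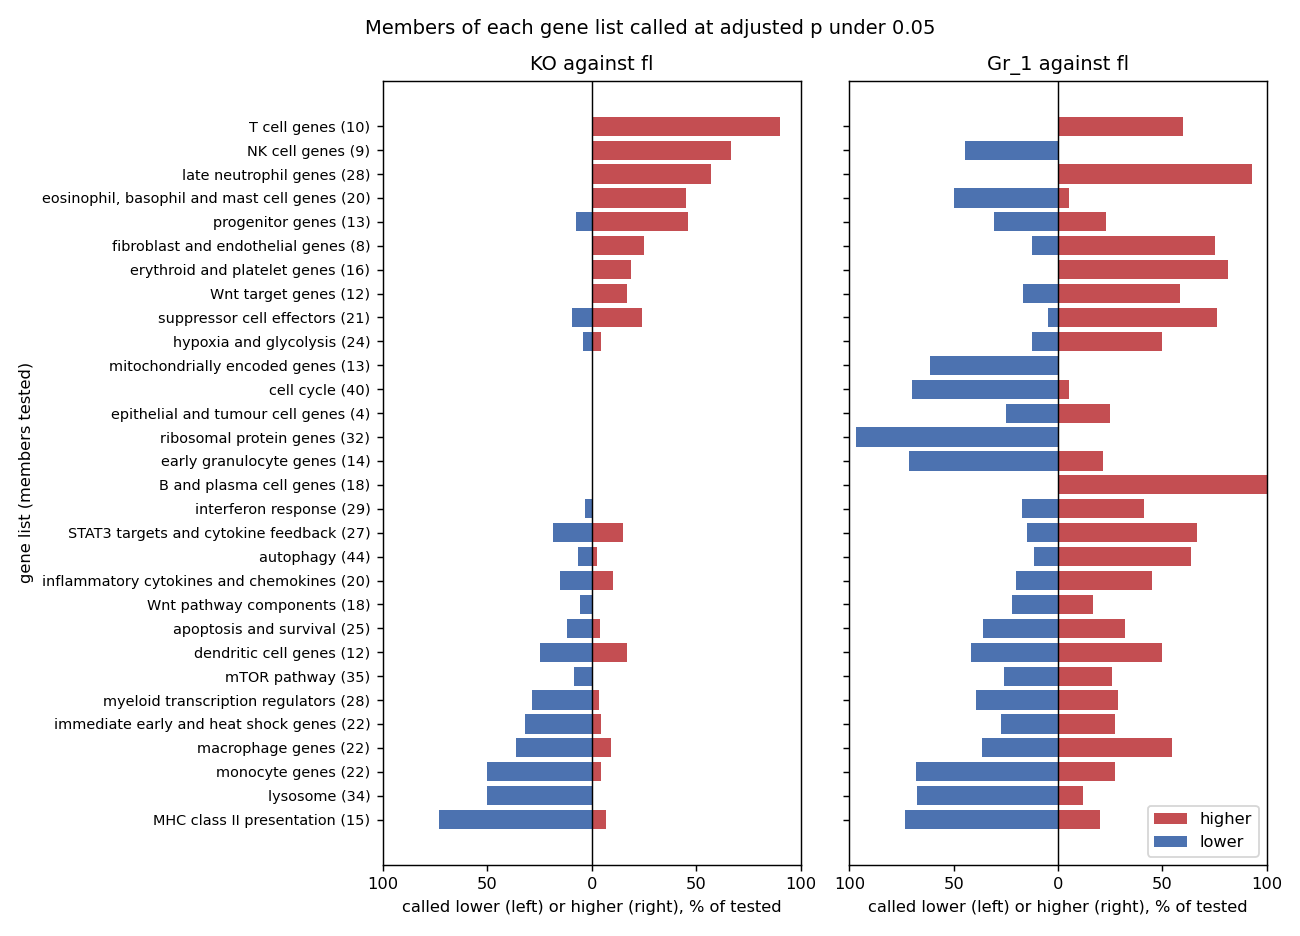
Members of each gene list called by limma at an adjusted p under 0.05, as percent of the members tested (in parentheses), with higher to the right in red and lower to the left in blue, for the libraries labelled KO against fl (left panel) and Gr_1 against fl (right panel). In the left panel T cell, NK cell and late neutrophil genes stand at the top and MHC class II presentation at the bottom; in the right panel the ribosomal protein genes lie on the lower side, with 31 of 32 lower.

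The comparison of Gr_1 with fl sets 2 groups of the same labelled genotype side by side. Gr_1 libraries carried far more RNA of mature neutrophil genes and far less of early granulocyte genes. Stfa2l1 rose to 201 ± 20.7 FPKM (log2 change 7.42 ± 0.27, adjusted p = 5.96e-07), Mmp9 rose 121-fold to 1621 ± 133 and Ly6g rose 68.5-fold to 684 ± 44.9. Mmp8 rose 54.9-fold to 1156 ± 37.2 FPKM and Il1b 39.4-fold to 413 ± 42.2. Fpr1, Asprv1, Scrg1, H2-Q10 and Arg2 also rose, with log2 changes from 5.10 to 6.20. Elane fell 25.9-fold to 92.7 ± 27.2 FPKM and the proteinase 3 gene Prtn3 20.7-fold to 44.1 ± 11.1, followed by the myeloperoxidase gene Mpo (14.8-fold) and the cathepsin G gene Ctsg (log2 change -3.41). Mgl2, Fn1, Nkg7, Gstm1, Cst7 and F13a1 fell between 8.47-fold and 15.8-fold. Socs3 rose by 2.94 ± 0.11 in log2(FPKM + 1) (adjusted p = 5.96e-07), with a ratio of mean FPKM of 9.44.

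Limma called 7550 of 12289 genes in this comparison, 3686 higher and 3864 lower in Gr_1, and 1660 of them changed by at least 1 on the log2 scale (1089 higher, 571 lower). Over all genes, called or not, the libraries of the groups lay apart in 67.5% (10% by chance). Small changes here depend on the scaling. The median change of all genes was -0.03 as deposited, -0.14 without the 10 most abundant genes, -0.27 scaled to library totals and -0.36 scaled to equal sums, where 1912 genes were higher and 6680 lower.

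Late neutrophil genes were higher in 26 of 28 members and lower in none (27 and 0 adjusted over the list alone, camera adjusted p = 2.46e-13, and adjusted p = 0.386 with an estimated correlation). Early granulocyte genes were lower in 10 of 14 and higher in 3 (10 and 3 adjusted over the list alone, camera adjusted p = 0.00437, and adjusted p = 0.452 with an estimated correlation). The 3 risers were Hp, Srgn and Igsf6, with Igsf6 at -0.04 scaled to equal sums and not called without Gr_1 B (adjusted p = 0.0591, 1 riser). Suppressor cell effectors rose in 16 of 21 and fell in 1, Tgfb1 (16 and 1 adjusted over the list alone, camera adjusted p = 2.46e-05, and adjusted p = 0.386 with an estimated correlation). Arg2 rose from 0.237 ± 0.108 to 41.5 ± 4.08 FPKM and Nt5e, which makes adenosine outside the cell, from 0.0341 ± 0.0104 to 7.72 ± 0.738. Arg1 and Nos2 stayed near the floor in all groups and were not tested. STAT3 targets and cytokine feedback genes rose in 18 of 27 and fell in 4 (19 and 4 adjusted over the list alone, camera adjusted p = 0.0014, and adjusted p = 0.386 with an estimated correlation). The interleukin 1 receptor antagonist gene Il1rn rose 15.3-fold and Stat3 rose by 0.57 ± 0.08 on the log2 scale, while the receptor genes Il10ra and Il6st fell.

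Autophagy genes were higher in 28 of 44 members and lower in 5 as deposited, but 17 were higher and 15 lower scaled to equal sums, where the median was -0.03 in place of 0.37 (28 and 5 adjusted over the list alone, camera adjusted p = 0.000657, and adjusted p = 0.386 with an estimated correlation). Map1lc3b rose from 18.8 ± 1.03 to 45.5 ± 0.578 FPKM (log2 change 1.23 ± 0.08, adjusted p = 6.35e-06) and the kinase gene Ulk1, which starts autophagosome formation, rose by 1.30 ± 0.07. Becn1 and Sqstm1 rose by 0.36 and 0.37 as deposited, but both had -0.03 scaled to equal sums. Mtor rose by 0.25, with -0.10 scaled to equal sums, and was not called without Gr_1 A, Gr_1 B, fl A or fl B (adjusted p up to 0.0743). The autophagy fallers were Uvrag, Atg14, Atg4c, Atg10 and Gabarapl1, of which 2 were left without Gr_1 A and 3 without Gr_1 B or fl A. Atg5 had a log2 change of -0.03 ± 0.07. Lysosome genes were lower in 23 of 34 and higher in 4, among them Ctsd and Ctsl (23 and 4 adjusted over the list alone, camera adjusted p = 0.000323, and adjusted p = 0.386 with an estimated correlation). The cathepsin gene Ctsb fell from 135 ± 3.25 to 58.7 ± 2.74 FPKM while Ctsd rose from 96.9 ± 10.4 to 194 ± 8.24. The mTOR pathway had 9 of 35 higher and 9 lower, and 2 higher and 23 lower scaled to equal sums (9 and 9 adjusted over the list alone, camera adjusted p = 0.949). Wnt pathway components had 3 of 18 higher and 4 lower, and 1 and 10 scaled to equal sums (3 and 4 adjusted over the list alone, camera adjusted p = 0.949), with Dvl1 higher and the co-receptor gene Lrp5 lower, and 5 were higher without KO A or KO B. Ctnnb1 had a log2 change of 0.06, and -0.34 scaled to equal sums. Wnt target genes had 7 of 12 higher and 2 lower, 4 and 4 scaled to equal sums, and 3 higher without Gr_1 A, Gr_1 B or Gr_1 C (7 and 2 adjusted over the list alone, camera adjusted p = 0.136).

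Monocyte genes were lower in 15 of 22 and higher in 6 (15 and 6 adjusted over the list alone, camera adjusted p = 0.0192, 0.34 scaled to equal sums, and adjusted p = 0.452 with an estimated correlation). Ly6c2 fell by 0.49 on the log2 scale while Itgam, the integrin CD11b of myeloid cells, rose by 1.21. MHC class II presentation had 11 of 15 lower and 3 higher (11 and 3 adjusted over the list alone, camera adjusted p = 0.00358, and adjusted p = 0.452 with an estimated correlation), with H2-Ab1 at 46.0 ± 4.61 FPKM. Macrophage genes had 12 of 22 higher, such as the complement gene C1qa, and 8 lower, such as Cd68 (12 and 8 adjusted over the list alone, camera adjusted p = 0.217, and called higher at 0.0124 scaled to equal sums). The macrophage marker gene Adgre1 fell by 0.84. B and plasma cell genes rose in 18 of 18 (18 adjusted over the list alone, camera adjusted p = 1.25e-06, and adjusted p = 0.386 with an estimated correlation), with the IgM heavy chain gene Ighm at 384 ± 22.6 against 171 ± 8.65 FPKM. T cell genes had 6 of 10 higher (6 adjusted over the list alone, camera adjusted p = 0.0377, and adjusted p = 0.386 with an estimated correlation), with Cd3d at 4.04 ± 0.652 FPKM. NK cell genes had 4 of 9 lower (4 adjusted over the list alone, camera adjusted p = 0.0331, and adjusted p = 0.71 with an estimated correlation), among them Nkg7, which early granulocyte precursors express too. Eosinophil, basophil and mast cell genes had 10 of 20 lower, such as Ear2 and Siglecf, and Hdc higher (10 and 1 adjusted over the list alone, camera adjusted p = 0.0406, and adjusted p = 0.71 with an estimated correlation). Erythroid and platelet genes had 13 of 16 higher (13 adjusted over the list alone, camera adjusted p = 0.00437, and adjusted p = 0.386 with an estimated correlation). Fibroblast and endothelial genes had 6 of 8 higher, such as the smooth muscle actin gene Acta2 and the collagen gene Col1a1, and Tie1 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.0432, and adjusted p = 0.386 with an estimated correlation). The T cell call was lost without Gr_1 A, Gr_1 B, Gr_1 C or fl A (adjusted p up to 0.0771), and the NK cell and eosinophil calls without Gr_1 A or fl C (up to 0.137, with 2 eosinophil, basophil and mast cell genes higher). The fibroblast call was lost without any Gr_1 library (up to 0.632), with 2 to 3 members higher, and without fl A, fl C or KO A (up to 0.0643). With the stricter filter the monocyte, T cell, NK cell, eosinophil and erythroid calls were lost (adjusted p = 0.0626, 0.669, 0.0947, 0.0626 and 0.0781). The T cell call was also lost with no filter (0.27), the fibroblast call with voom (0.0532), and the NK cell and eosinophil calls scaled to equal sums (0.303 and 0.2365).

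Ribosomal protein genes fell in 31 of 32 members (32 adjusted over the list alone, median log2 change -0.97, camera adjusted p = 2.97e-09, and adjusted p = 0.452 with an estimated correlation), with Rps19 at 69.3 ± 4.94 against 152 ± 14.2 FPKM. Cell cycle genes fell in 28 of 40 and rose in 2 (29 and 2 adjusted over the list alone, camera adjusted p = 2.33e-05, and adjusted p = 0.386 with an estimated correlation). The replication licensing gene Cdt1 fell 2.10-fold, and the risers were Cdc25b and E2f2, of which E2f2 had -0.15 scaled to equal sums and was not called without Gr_1 A, Gr_1 B, fl A, fl B or KO C. Mitochondrially encoded genes had 8 of 13 lower (8 adjusted over the list alone, camera adjusted p = 0.0704, and 0.00152 without fl C). Hypoxia and glycolysis genes had 12 of 24 higher and 3 lower, and 4 and 10 scaled to equal sums (12 and 3 adjusted over the list alone, camera adjusted p = 0.112), with the lactate exporter gene Slc16a3 at 147 ± 14.3 against 30.9 ± 3.09 FPKM. Interferon response genes had 12 of 29 higher and 5 lower, and 7 and 11 scaled to equal sums (12 and 5 adjusted over the list alone, camera adjusted p = 0.576), with 8 lower without KO A or KO B. Inflammatory cytokines and chemokines had 9 of 20 higher and 4 lower, and 7 and 7 scaled to equal sums (9 and 4 adjusted over the list alone, camera adjusted p = 0.355), with 7 lower without Gr_1 C. Apoptosis and survival genes had 8 of 25 higher, such as Mcl1, and 9 lower (8 and 9 adjusted over the list alone, camera adjusted p = 0.977). Immediate early and heat shock genes had 6 of 22 higher and 6 lower (6 and 5 adjusted over the list alone, camera adjusted p = 0.96). Myeloid transcription regulators had 8 of 28 higher, such as Bcl6, and 11 lower, such as Irf8 (8 and 11 adjusted over the list alone, camera adjusted p = 0.606), and Cebpb was not called (adjusted p = 0.199). Dendritic cell genes had 6 of 12 higher and 5 lower, and 4 and 5 scaled to equal sums (6 and 5 adjusted over the list alone, camera adjusted p = 0.98). Progenitor genes had 3 of 13 higher and 4 lower (3 and 4 adjusted over the list alone, camera adjusted p = 0.949). Of 4 epithelial and tumour cell genes, Lcn2 rose and Spint2 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.949), with 2 lower without fl B.

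In the libraries labelled KO set against Gr_1, early granulocyte genes were higher and late neutrophil genes lower. Elane was 25.7-fold higher, at 2387 ± 745 against 92.7 ± 27.2 FPKM (log2 change 4.66 ± 0.29, adjusted p = 2.06e-05). Prtn3 was 20.6-fold higher, Mpo 17.5-fold, Ctsg 14.8-fold and Nkg7 10.2-fold. After Lyz2, the largest falls were those of Vpreb1 and Igll1, parts of the pre-B cell receptor, at 3.11 ± 1.65 against 44.1 ± 8.32 and 2.66 against 36.2 ± 7.92 FPKM, with Gpr27 and Stfa2. Socs3 fell by 2.01 on the log2 scale (adjusted p = 1.65e-05). Map1lc3b fell by 1.19 and Cebpb fell by 1.10 (adjusted p = 0.00305). Itgam, Stat3, Sqstm1, Becn1 and Mtor had log2 changes of -1.03, -0.61, -0.38, -0.31 and -0.28, the last 3 at 0.05, 0.11 and 0.09 and not called scaled to equal sums, and Ly6g fell by 2.75. Ly6c2 rose by 0.35 and Adgre1 by 0.59, and Ctnnb1 and Atg5 were not called (-0.12 and -0.01), though Ctnnb1 was called lower without fl C (adjusted p = 0.0339). Limma called 6843 genes, 3287 higher and 3556 lower, 1136 of them by at least 1 on the log2 scale (287 and 849), and over all genes, called or not, the groups' libraries lay apart in 68.2% (10% by chance). Directions of small changes flipped with the scaling, since the median of all genes moved from 0.01 as deposited to 0.29 scaled to library totals and 0.36 scaled to equal sums, where 6737 genes were higher and 1598 lower.

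Camera called 13 of the 30 lists between the libraries labelled KO and Gr_1. Early granulocyte genes had 10 of 14 higher and Hp lower (10 and 1 adjusted over the list alone, adjusted p = 0.000172) and late neutrophil genes 27 of 28 lower (27 adjusted over the list alone, adjusted p = 3.63e-11), both at an adjusted p = 0.437 with an estimated correlation. Ribosomal protein genes had 30 of 32 higher (30 adjusted over the list alone, adjusted p = 3.73e-09, and adjusted p = 0.55 with an estimated correlation). Cell cycle genes had 27 of 40 higher and 2 lower (27 and 2 adjusted over the list alone, adjusted p = 7.6e-07), NK cell genes 9 of 9 higher (9 adjusted over the list alone, adjusted p = 3.72e-05), and eosinophil, basophil and mast cell genes 18 of 20 higher and 1 lower (18 and 1 adjusted over the list alone, adjusted p = 1.73e-06). Each of these 3 had an adjusted p = 0.437 with an estimated correlation. B and plasma cell genes had 14 of 18 lower (14 adjusted over the list alone, adjusted p = 9.41e-07), suppressor cell effectors 17 of 21 lower and 3 higher (17 and 3 adjusted over the list alone, adjusted p = 9.71e-05), STAT3 targets and cytokine feedback genes 20 of 27 lower and 2 higher (21 and 3 adjusted over the list alone, adjusted p = 0.000109) and macrophage genes 14 of 22 lower and 4 higher (14 and 5 adjusted over the list alone, adjusted p = 0.0103, and 0.0723 with the stricter filter). These too had an adjusted p = 0.437 with an estimated correlation. The risers among the suppressor cell effectors numbered 1 without KO A, KO C, Gr_1 A or Gr_1 B, and among the STAT3 targets 4 without Gr_1 C. Autophagy genes had 29 of 44 lower and 3 higher, but 13 and 12 scaled to equal sums (29 and 3 adjusted over the list alone, adjusted p = 1.09e-05, and adjusted p = 0.387 with an estimated correlation), and 1 was higher without KO B, KO C, Gr_1 A or Gr_1 B. Progenitor genes had 7 of 13 higher and 2 lower (9 and 2 adjusted over the list alone, adjusted p = 0.0326, 0.058 without Gr_1 A, 0.0837 with the stricter filter and 0.178 scaled to equal sums), at an adjusted p = 0.437 with an estimated correlation. Mitochondrially encoded genes had 8 of 13 higher (8 adjusted over the list alone, adjusted p = 0.0406, up to 0.0855 without Gr_1 A, Gr_1 C, KO A or KO B, and 0.277 scaled to equal sums), at an adjusted p = 0.62 with an estimated correlation.

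Changes from fl ran in the same direction in both other groups for most called genes. Of the 551 genes higher in the libraries labelled KO than in fl, 441 were also higher in Gr_1 and 16 were lower. Of the 801 genes lower, 635 were also lower in Gr_1 and 40 higher. Both comparisons use the same fl libraries, so part of these counts may come from them. Groups simulated with no effect shared at most 1 call in either direction, and independent lists of these sizes would share 165 and 252, but the former leaves out the effects and the latter the shared libraries. The libraries labelled KO lay between fl and Gr_1 for 405 of the rising and 525 of the falling genes. Across the 12289 genes, which are not independent replicates, the log2 changes had r = 0.614 and rho = 0.532. Groups simulated with no effect gave r = 0.50, with a covariance of 0.0132 against 0.169 in the data. The correlation was 0.489 without KO A, against 0.442 simulated for those libraries, and 0.704 without KO B, against 0.4475. Without fl A, fl B or fl C it was 0.6365, 0.620 and 0.602, close to the 0.602, 0.595 and 0.598 simulated, with covariances from 0.167 to 0.190 against at most 0.01925 simulated. Late neutrophil genes lay along this shared direction, T cell and NK cell genes rose in the libraries labelled KO with log2 changes in Gr_1 on both sides of 0, and early granulocyte genes had changes near 0 in the libraries labelled KO and down to -4.70 in Gr_1.

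**Figure D3:**
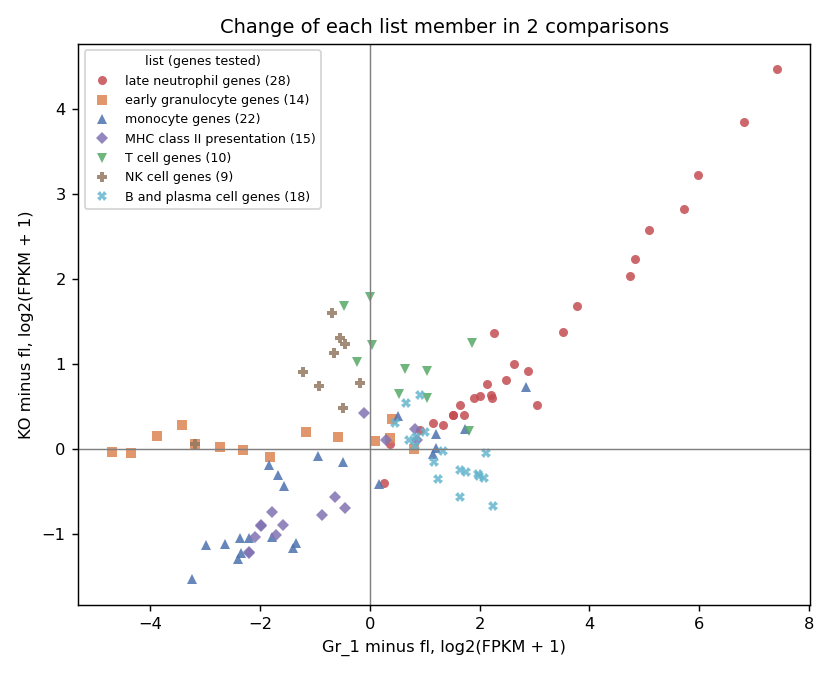
Log2 change from fl of each tested member of 7 gene lists, with Gr_1 minus fl on the x axis and the libraries labelled KO minus fl on the y axis (log2 of FPKM + 1), 1 point per gene and 1 colour and shape per list. Late neutrophil genes run along a rising line to 7.42 and 4.46, early granulocyte genes spread along the x axis, and T cell and NK cell genes lie above it.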

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

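Scaling to library totals, scaling to equal sums and voom were chosen after the results were seen; the other alternatives were not. The rise of Socs3 from fl to the libraries labelled KO was called under all 21 alternatives run, with log2 changes from 0.84 to 1.09 and adjusted p from 0.000571 to 0.0105. For single named genes, 4870 values stayed on their side of the threshold, 190 kept the direction and lost the call, 18 gained one and 19 reversed. A change of direction was counted as reversed only where the main or the alternative fit called the gene. Values that changed direction without a call in either fit are among the 4870. For gene lists the counts by the same rule were 1900, 103, 61 and 0, so lists that changed direction without a call are among the 1900.

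The count of 1352 genes between the libraries labelled KO and fl was 797 when only those 2 groups entered the fit, which also reduced the genes tested to 11586. The same alternative gave 7224 for Gr_1 against fl and 7116 for KO against Gr_1; the cause was not tested. It ranged from 573 (without KO C) to 1261 (without KO B) when 1 library was left out. With a change of at least 1 on the log2 scale also required, the counts were 228 for KO against fl, 1660 for Gr_1 against fl and 1136 for KO against Gr_1, which is by construction of that threshold. With the title letter as a block the counts were 1037, 7280 and 6469. Libraries of different groups that share a letter were not more alike than others as a set. Among fl and KO pairs, however, fl A with KO A gave the highest r of all (0.140). The B and C pairs of fl and KO had -0.0119 and 0.0752, and fl C with KO B, of unlike letters, had 0.0818. The correlation of the changes of the libraries labelled KO and Gr_1 from fl ranged from 0.489 (without KO A) to 0.704 (without KO B), against 0.614 with all libraries.

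Camera with an estimated correlation called 0 lists in each of the 3 comparisons, against 16, 16 and 13 with the preset one. At an unadjusted p under 0.05 it gave 6, 2 and 1. The stricter filter left 10 lists called for Gr_1 against fl, and fry called 23 for KO against Gr_1; the cause was not tested.

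All values of named genes counted as reversed came from rescaling, which moves every gene of a library by the same factor. For Gr_1 against fl, scaling to library totals gave log2 changes of -0.033 for E2f2, -0.23 for Ctnnb1 and -0.00098 for Mtor. Scaling to equal sums gave -0.045 for Igsf6, -0.15 for E2f2, -0.34 for Ctnnb1, -0.033 for Becn1, -0.033 for Sqstm1 and -0.10 for Mtor. For KO against Gr_1, scaling to library totals gave 0.21 for Ctnnb1, 0.015 for Becn1, 0.31 for Atg5 and 0.0075 for Mtor. Scaling to equal sums gave 0.30 for Ctnnb1, 0.11 for Becn1, 0.053 for Sqstm1, 0.40 for Atg5 and 0.092 for Mtor, and Atg5 had 0.19 without the 10 most abundant genes.

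Depth limits what can be said of weakly expressed genes. For a gene with 1 kilobase of exon, 3 fragments correspond to between 0.136 and 0.187 FPKM. Mir155hg, Arg1 and Nos2 were not tested because they did not reach 1 FPKM in 3 libraries.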

Other observations

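A few genes of basophils and lymphocytes were higher in the libraries labelled KO than in either other group. The genes below were chosen after their values were seen, and no list was tested against both groups at once. Prss34, a basophil protease, had 234 ± 32.6 FPKM in the libraries labelled KO against 79.9 ± 38.5 in fl, and the related protease gene Mcpt8 had 116 ± 15.6 against 42.4 in fl and 35.5 in Gr_1. The IgE receptor gene Fcer1a had 16.7 ± 11.2 against 2.97 and 1.66. The T cell receptor gene Trbc1 had 5.96 against 1.24 and 0.579, and the lymphocyte chemokine gene Xcl1 had 7.67 against 1.63 and 0.698. Among genes lower than in both groups were Ifitm3, an antiviral membrane protein gene, at 428 ± 113 FPKM against 769.5 and 757, the galectin gene Lgals3 at 155 against 257 and 305, and the retinoic acid receptor gene Rara at 16.8 against 28.6 and 39.1. Limma called 100 genes higher and 154 lower against both groups. The 2 comparisons share the libraries labelled KO, and groups simulated with no effect shared 0 calls in either direction. Independent lists of these sizes would share 147 and 232, which leaves out the shared libraries.

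All tests in this part were chosen only after the result was seen. The first pattern is library KO C, whose levels lay between those of KO A and KO B for 292 of the 337 genes that differed by over 1 on the log2 scale between these 2. This was 86.6%, against at most 69.3% for any other library within its group, which restates the pattern and leaves RNA of the animals of both open. Its Xist level was 45.0% of that in KO B and its Y-linked level 53.5% of that in KO A, which argues against 1 animal of 1 sex. Over the 337 genes KO C sat at a median of 0.496 of the way from KO A to KO B in FPKM (quartiles 0.343 and 0.601). The mean chi-square per gene was 13.4 between KO C and KO A, 14.4 between KO C and KO B, and 45.3 between KO A and KO B. A pool of other animals of both sexes stays open too. If KO C shares RNA with KO A and KO B, the spread among these 3 libraries is too small, and so are the p-values that rest on it.

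The second pattern is the rise of late neutrophil genes with the fall of monocyte and macrophage genes in the libraries labelled KO. The share of the Gr_1 kind was estimated from 17 genes outside the gene lists. These had at least 20 FPKM in Gr_1 and at least 20 times their fl level. Among them were Fpr1, Asprv1, Scrg1 and H2-Q10, which also had some of the largest rises in the libraries labelled KO. The share came to 19.0%, 6.36% and 13.1% in KO A, KO B and KO C. RNA of the Gr_1 libraries mixed in is argued against by Lyz2, which reached at most 8.81% of the level that share would bring. A share of cells of that kind among the libraries' own cells could account for the late neutrophil genes, whose observed change exceeded the expected one by a median of 0.10 on the log2 scale. This closeness cannot tell such a share from a joint rise of these genes within cells, since the share was read from genes that rose with them. Such a share could not account for the fall of the monocyte and macrophage lists. There the median difference was -0.41 over all 22 monocyte genes (quartiles -0.97 and -0.10) and -0.60 over all 22 macrophage genes (quartiles -0.73 and -0.02). It was -0.94 over the 19 members chosen because they fell. An effect of the labelled genotype, and of sex, stays open and untested.

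The third pattern is Lyz2, far lower, with Socs3 not lower in the libraries labelled KO. Fragments counted for the paralog Lyz1 are argued against, since Lyz1 and Lyz2 together held 1.01% of the fl fragments. Disrupted Lyz2 copies, as in mice with Cre recombinase placed at that gene, are consistent with an even loss (highest over lowest library 1.12) and with the neighbouring genes Cpsf6 and Yeats4 at 1.14 and 1.07 times their fl level, though the labels name no such allele. The next values assume that cells of the Gr_1 kind carry Socs3 at its level in the Gr_1 libraries, which are labelled wild type. With all other cells at the fl level, the estimated share would bring Socs3 to 9.80, 5.78 and 7.91 FPKM in KO A, KO B and KO C. These levels are near the 9.23, 6.76 and 8.37 observed. Whether such cells among the libraries' own cells keep that Socs3 level was not tested. Loss of Socs3 hidden by RNA of such cells stays open. On the same assumption, the level left without that RNA was 0.811, 1.28 and 1.14 of fl in KO A, KO B and KO C. At the upper quartile of the share, however, it was 0.444 in KO A (1.12 and 0.962 in KO B and KO C). A persisting transcript and a wrong label stay open untested.

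For each comparison the 6 libraries can be split into groups of 3 in 10 ways, so the share of splits with as many called genes cannot go below 0.1. Only 1 of the 10 splits, the real one, gave as many genes in each comparison. The real counts were 1352, 7550 and 6843, and the highest of the other splits called 0 each with limma.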
